A study of Mus musculus with 18 samples.

How the data were processed

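RNA from preparations labelled as bone marrow mesenchymal stromal cells, of 18 mice was measured on 1 array per mouse: 5 BALB/c and 5 NeuT mice of 12 weeks, and 4 BALB/c and 4 NeuT mice of 24 weeks. Per the labels the cells were bead-purified from femurs and tibias, checked by flow cytometry for CD45, CD29 and CD44, and their total RNA was extracted with a miRNeasy kit and labelled with biotin. The replicates of a group are different mice. The deposited values are on the log2 scale, 1 signal per probe set. The submitters' processing notes name RMA (background correction, quantile normalisation and summarisation of probes) and the Transcriptome Analysis Console; their versions and the genome build are not given in the sources used here, so no coordinates are printed.

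The table held 29129 probe sets. Of these 19572 were matched with 1 gene symbol, and 2634 transcript clusters without a name here, 5222 negative, 1324 positive and 377 other controls were left out. For the 55 genes with more than 1 probe set the one with the highest mean over all arrays was kept, which left 19505 genes. No filter on dim genes was applied, since the table has no detection calls. The number of arrays limits the precision.

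A linear model with 1 mean per group was fitted to each gene with limma 3.58.1 in R 4.3.3, with default moderation of the variances (14 residual and 8.68 prior degrees of freedom). The contrasts were NeuT minus BALB/c at 12 and at 24 weeks, the difference of these effects, and 24 minus 12 weeks in each mouse model. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Age is confounded with any processing batch of the 12- and 24-week mice, which the labels do not give.

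The tests, 50 lists of cell type markers and pathway genes (723 distinct genes measured) and the rule for naming genes were fixed before the data were examined. The lists were tested with limma's camera (preset inter-gene correlation 0.01, adjusted over the lists), and again with an estimated correlation and with fry. The list tests of the 2 age contrasts were added later. The rule names, among genes past the threshold, the 12 higher and 12 lower with the largest change for NeuT against BALB/c at each age and 6 and 6 for the other contrasts, filled to 5 by smallest p. Per list it names up to 4 genes past the threshold by size, or else the 2 with the smallest p as values. Erbb2 and antigen genes used in the purification are always given; Ly6g, Xist and Ddx3y were not analysed here, and genes with provisional names were passed over. On simulated data with 200 changed genes the fit recovered 82.4%, 80.6% and 48% of log2 changes of 0.5 at 12 weeks, at 24 weeks and for the difference. The simulated genes varied independently, with the same SD in every group and array. The real genes and arrays do not, so recovery in the real data is not known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

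Alternatives were other normalisations (a further quantile normalisation, cyclic loess, median centring), a filter on dim genes, all probe sets with controls, the mean of a gene's probe sets, moderation with a trend and robust variances, array weights, fits on only the 2 groups compared, a blood-cell covariate, an unmoderated test per gene with unequal variances, fold thresholds, and leaving out each array in turn. For genes named by size, as antigens or from lists the number of fits without 1 array in which a call ended is given where it was no smaller than the number in which it held. Chosen after seeing the data were the fits without the 3 arrays that correlate least with the others, with 2 covariates (neutrophil and B-cell list means), with mouse ID rank (each of 2 IDs the labels give for 1 mouse), over all transcript clusters, and the correlation of effects without Peg3.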

Results

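Transcript levels were measured in preparations labelled as bone marrow mesenchymal stromal cells (BM-MSCs, marrow cells that form bone and fat and support blood formation) from 18 mice, 1 array per mouse. NeuT mice carry an activated rat Erbb2 (HER2/neu) transgene and develop mammary tumours, and BALB/c mice were the controls. The labels call the NeuT mice of both ages tumour-bearing, so effects of the transgene and of the tumours cannot be told apart. At 12 weeks of age 5 NeuT and 5 BALB/c mice were compared, and at 24 weeks 4 NeuT and 4 BALB/c mice. The cells came from femurs and tibias by depleting blood cells with antibody-coated beads, against antigens that included CD45, CD11b, CD11c, CD3, Gr1 and B220. The comparisons ask how this preparation differs between the mouse models at each age, and whether that difference changes with age.

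The arrays were alike in scale, with median log2 signals between 8.43 and 8.56 over 19505 genes. Their number limits the precision, and without detection calls no gene is called absent. Negative control probe sets had a median log2 signal of 7.34 and the genes 8.50. For genes with a group mean under the control median the log2 values compare signals, and the size of the change in transcript level is not known: Peg3, Usp29, Chil3, Clec4a3, Mmp9, Il21r, Idi1, Ifi211, Rtp4, Erbb2, Oosp2 and Tmem267. Correlations between arrays ran from 0.978 to 0.997 across genes, which are not independent replicates. The arrays with the lowest median correlation with the others were NeuT 12-week replicate 4 (0.988), BALB/c 24-week replicate 3 (0.988) and NeuT 24-week replicate 1 (0.991). Itgb1 and Cd44, which encode the CD29 and CD44 antigens used to characterise the cells, did not pass at either age (log2 differences of 0.011 and -0.057 at 12 weeks, 0.013 and 0.13 at 24 weeks). Itgb1 read 11.46 ± 0.084 (SD, n = 5) in BALB/c and 11.47 ± 0.081 in NeuT mice at 12 weeks, and Cd44 read 11.89 ± 0.034 and 11.83 ± 0.15. Ptprc, which encodes the depleted antigen CD45, gave signals of 11.70 to 12.45, with log2 differences of -0.30 at 12 weeks (adjusted p = 0.0880) and -0.22 at 24 weeks (adjusted p = 0.410). Elane and Mpo, known from neutrophil precursors, gave 13.62 to 14.24 and 13.45 to 14.02. In every array Ptprc, Elane and Mpo lay above 10.4, the 95th percentile of the negative controls. The preparations thus held blood-cell transcripts at high signal despite the depletion. The top Elane signal, 14.24, was the highest of any gene in any array. Of genes known from stromal cells, Pdgfrb gave 7.96 to 8.92, Col1a2 8.25 to 8.86 and Cxcl12 9.04 to 9.45, all under 10.4. Signals of different probe sets do not give the share of each cell type. Elane, Mpo, Pdgfrb, Col1a2 and Cxcl12 were named after their values were seen. Cd3e, which encodes part of the depleted antigen CD3, had a value of -0.13 at 12 weeks (adjusted p = 0.559). Itgax, which encodes CD11c, had values of 0.13 and 0.11 (adjusted p = 0.485 and 0.722). For Erbb2, the mouse counterpart of the transgene, the log2 difference was 0.08 ± 0.11 (SE) at 12 weeks (adjusted p = 0.720) and 0.057 ± 0.13 at 24 weeks (adjusted p = 0.883). All its signals lay under the median of the negative controls, so these differences say nothing about its expression, and probes for the mouse gene need not read the rat transgene.

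At 12 weeks NeuT preparations differed from controls most in Peg3 (Entrez gene 18616), an imprinted zinc-finger gene, which was higher in NeuT mice (log2 fold change 4.01 ± 0.13 SE, adjusted p = 8.07e-16, n = 5 and 5). Peg3 read 6.63 ± 0.16 (SD) in BALB/c and 10.65 ± 0.34 in NeuT mice. Its signals in BALB/c mice lie under the median of the negative controls, so the size of the change is not known exactly. Usp29, the imprinted neighbour of Peg3, had a log2 difference of 1.08 (adjusted p = 9.02e-06), with all signals under that median. Chil3, a chitinase-like protein gene of myeloid cells, rose by 1.96 on the log2 scale (adjusted p = 0.00980) and Mmp8, the neutrophil collagenase gene, 3.502-fold (adjusted p = 0.00976). Ltf and Lcn2, which encode lactoferrin and lipocalin 2 of the granules, rose 2.86-fold and 2.66-fold (adjusted p = 0.0343 and 0.0375). Ccr2, the chemokine receptor of inflammatory monocytes, rose 2.38-fold (log2 fold change 1.25 ± 0.13, adjusted p = 9.02e-06). On the log2 scale rises were also seen for Ms4a6d (1.64), Clec4a3 (1.53), Ms4a4c (1.52), Clec5a (1.20), Aif1 (1.18) and Bex6 (1.21). As for Peg3, the BALB/c means of Chil3 and Clec4a3 lie under the median of the negative controls. Leaving out 1 array ended the call of Lcn2 in 8 of 10 fits and of Ltf in 7.

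The gene that fell most at 12 weeks was Hmox1 (Entrez gene 15368), which encodes the haem-degrading enzyme haem oxygenase 1. It fell by 1.15 on the log2 scale (SE 0.12, adjusted p = 9.02e-06), from 9.84 ± 0.20 (SD) in BALB/c to 8.69 ± 0.21 in NeuT mice. Srxn1, which encodes the antioxidant enzyme sulfiredoxin, had a log2 fold change of -0.61 ± 0.079 (adjusted p = 0.000233). Further genes called lower, on the log2 scale, were Nuak1 (-0.93), Slc25a18 (-0.71), Il21r (-0.69), Dtx1 (-0.64), Ephx1 (-0.64), Jchain (-0.61), Tmod1 (-0.59), Myo1e (-0.58), Hivep2 (-0.58) and Mmrn1 (-0.57), of which Il21r has a NeuT mean under the control median. Without 1 array the call ended in 9 of 10 fits for Nuak1, 8 for Il21r, 7 for Myo1e, 6 each for Dtx1, Jchain, Tmod1 and Mmrn1, and 5 for Hivep2, while Hmox1 passed in each. In all, 749 genes changed at an adjusted p under 0.05, 615 higher and 134 lower in NeuT mice, 120 of them by at least 1.5-fold. The higher share of 82.1% was 67.4% after a further quantile normalisation and 68.6% after cyclic loess. In 540 of the genes that changed the 2 groups did not overlap. Over all genes they did not overlap in 7.46%, against 0.794% by chance. With each array's means of the neutrophil and B-cell lists as covariates, chosen after seeing the data, 4 genes passed, namely Peg3, Usp29, Hmox1 and Ccr2. In a fit over all probe sets 1.98% of those named, 0.996% of the negative controls and 1.51% of the positive controls passed. Without BALB/c 12-week replicate 2, 230 genes passed, and without NeuT 12-week replicate 5, 1363.

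**Figure D1:**
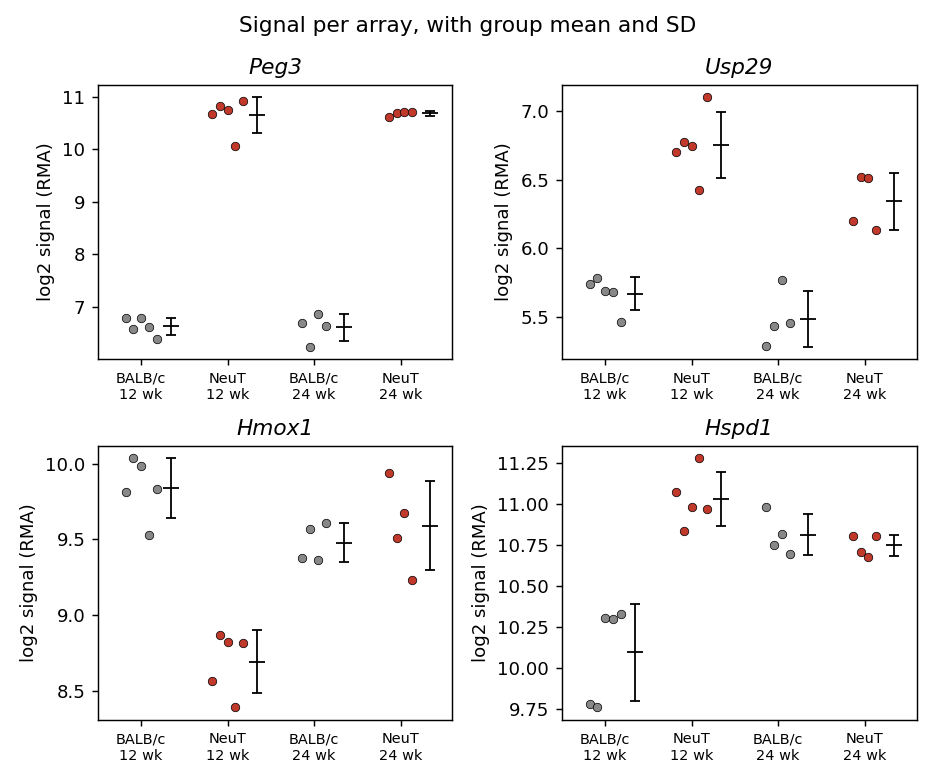
Log2 signal per array (y axis) of Peg3, Usp29, Hmox1 and Hspd1 in the 4 groups (x axis), where each point is 1 mouse and the bar shows the group mean and SD. Peg3 lies between 6.25 and 6.87 in all BALB/c mice and between 10.06 and 10.93 in all NeuT mice.

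The fixed gene lists were compared next, blood-cell lists first. Of 15 neutrophil genes 5 rose at 12 weeks, Chil3, Mmp8, Ltf, Lcn2 and Cxcr2 (0.47), the last outside the naming rule and named after its value was seen; none fell and 10 did not pass, with 12 higher adjusted over the list alone. The median log2 fold change of the list was 0.59 (camera adjusted p = 4.38e-09; adjusted p = 0.271 with an estimated correlation). Of 15 monocyte and macrophage genes 4 rose, Ccr2, Lyz2 (0.76), Fcgr1 (0.50) and Csf1r (0.46), and 1 fell, the complement gene C1qc (-0.33), named after its value was seen, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00195; adjusted p = 0.271 with an estimated correlation). The granulocyte-monocyte progenitor list had 2 of 10 higher, Nkg7 and Ms4a3, and 5 higher adjusted over the list alone (camera adjusted p = 0.00370; adjusted p = 0.402 with an estimated correlation). In the mast cell, basophil and eosinophil list 2 of 14 rose, Ms4a2 and Fcer1a, subunit genes of the high-affinity IgE receptor, with 4 higher adjusted over the list alone (camera adjusted p = 0.000505; adjusted p = 0.280 with an estimated correlation). Leaving out 1 array ended the call in 9 of 10 fits for Ms4a3, in 7 each for Cxcr2 and Csf1r, in 6 for Nkg7, and in 5 for Lyz2. The B-cell list was lower as a whole, with a median of -0.32 (camera adjusted p = 0.00866; adjusted p = 0.515 with an estimated correlation). None of its 14 genes passed over all genes and none adjusted over the list alone, and Cd79b and Pax5 had values of -0.65 and -0.75 (adjusted p = 0.100 and 0.111). The mean of this list shifted by -0.33, and by -0.15 without NeuT 12-week replicate 1.

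Several stress and inflammatory lists were higher in 12-week NeuT mice. Of 10 heat-shock genes 6 rose and none fell, with 6 higher adjusted over the list alone. Hspb1 rose by 1.01 and Hspd1, the mitochondrial chaperonin gene, by 0.93 on the log2 scale, and the list median was 0.40 (camera adjusted p = 3.60e-09; adjusted p = 0.271 with an estimated correlation). Of 20 immediate-early genes, which also respond to tissue dissociation, 7 rose, among them the transcription factor genes Fos (0.89), Atf3 (0.65), Egr1 (0.54) and Klf4 (0.51), with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.21e-07; adjusted p = 0.271 with an estimated correlation). Among 23 inflammatory cytokines and chemokines 6 rose, including Ccl4 (0.93), Il1b (0.74), Cxcl2 (0.47) and Ccl3 (0.41), with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00954; adjusted p = 0.271 with an estimated correlation). The type I interferon list had 4 of 25 higher, Rtp4, Oas1a, Oas2 and Zbp1, and 7 higher adjusted over the list alone (camera adjusted p = 0.00102; adjusted p = 0.271 with an estimated correlation). In the MHC class I list 3 of 13 rose, the immunoproteasome subunit genes Psmb8, Psmb9 and Psmb10, with 6 higher adjusted over the list alone (camera adjusted p = 0.00156; adjusted p = 0.271 with an estimated correlation). The antioxidant and NRF2 target list was lower: Hmox1, Srxn1 and Gclc (-0.43) fell out of 17, with 8 lower adjusted over the list alone (camera adjusted p = 0.00396; adjusted p = 0.271 with an estimated correlation). Single calls ended without 1 array in 9 of 10 fits each for Cxcl2, Zbp1 and Gclc, in 7 for Ccl3, in 6 for Psmb10, and in 5 for Egr1. The lists for the unfolded protein response, NF-kB targets and p53 and senescence did not pass, with medians of 0.11, -0.055 and 0.042 (camera adjusted p = 0.0640, 0.707 and 0.549). Of their genes 5 of 18, 1 of 16 and 2 of 14 rose, and 1, 1 and 0 fell; adjusted over the list alone 7, 1 and 2 were higher and 3, 3 and 0 lower.

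Metabolic lists were higher at 12 weeks too. Hypoxia and glycolysis genes rose in 4 of 23 cases, Hk2, Pgk1, Egln1 and P4ha1, with 7 higher adjusted over the list alone (camera adjusted p = 0.000251; adjusted p = 0.271 with an estimated correlation). In the oxidative phosphorylation list 3 of 29 rose, Ndufs1, Ndufb3 and Atp5c1, with 4 higher adjusted over the list alone (camera adjusted p = 6.97e-05; adjusted p = 0.433 with an estimated correlation). Cholesterol synthesis genes that rose were Idi1, Fdps, Cyp51 and Hmgcs1 of 14, with 5 higher adjusted over the list alone (camera adjusted p = 0.00259; adjusted p = 0.383 with an estimated correlation). The proteasome list had 1 of 19 higher, Psma7, and 2 higher adjusted over the list alone (camera adjusted p = 0.000530; adjusted p = 0.469 with an estimated correlation). In these 4 lists leaving out 1 array ended the call in 9 of 10 fits each for P4ha1, Atp5c1 and Fdps, in 8 each for Ndufb3 and Psma7, and in 7 for Hmgcs1. Endothelial genes were lower as a list, and Cdh5, the VE-cadherin gene, fell alone among 13, with 2 lower adjusted over the list alone (camera adjusted p = 0.00976; adjusted p = 0.271 with an estimated correlation). The megakaryocyte and platelet list was lower too, with none of 11 past the threshold over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.392 with an estimated correlation). The stromal markers, in the list for MSCs and CXCL12-abundant reticular cells, had a median of -0.00068 at 12 weeks (camera adjusted p = 0.881), with none of 19 past the threshold and 2 higher adjusted over the list alone. In all 17 of 50 lists passed at 12 weeks, 13 upwards and 4 downwards. With fry, which asks whether the genes of a list move one way on balance, 9 passed, and with camera and an estimated correlation 0, with 5 at an unadjusted p under 0.05.

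At 24 weeks Peg3 again had the largest change and was higher in NeuT mice (log2 fold change 4.08 ± 0.14 SE, adjusted p = 6.76e-15, n = 4 and 4), again from BALB/c signals under the median of the negative controls, and Usp29, all of whose signals lie under it, had a log2 difference of 0.85 (adjusted p = 0.00264). Ltf rose 3.52-fold (adjusted p = 0.0427) and Mmp9, a gelatinase gene of neutrophil granules, by 1.07 on the log2 scale (adjusted p = 0.0430). Tslp, which encodes an epithelial and stromal cytokine acting on dendritic and lymphoid cells, rose 1.82-fold (log2 fold change 0.87 ± 0.11, adjusted p = 0.000293). On the log2 scale Clec4a2 (1.01), Slco4c1 (0.96), Pilra (0.94), Mctp1 (0.91) and Clec5a (0.88) rose, as did the interferon-inducible genes Ifi44l (0.92) and Ifi211 (0.86), the last from a BALB/c mean under the control median. Itgam, which encodes the depleted antigen CD11b, rose by 0.59 (adjusted p = 0.0427); at 12 weeks its value was 0.39 (adjusted p = 0.0838), and the difference of effects was 0.20 (adjusted p = 0.916). Itgam passed in 8 of 23 alternatives at 24 weeks and in 2 of 26 at 12 weeks. Leaving out 1 array ended the 24-week call in 7 of 8 fits each for Itgam, Ltf and Pilra, in 6 each for Mmp9, Clec5a and Ifi44l, and in 4 each for Clec4a2 and Mctp1.

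At 24 weeks Gzma, the granzyme A gene of cytotoxic T and NK cells, fell by 1.33 on the log2 scale (SE 0.19, adjusted p = 0.00264), from 9.39 ± 0.31 (SD) to 8.06 ± 0.51. The B-cell transcription factor gene Spib had a log2 fold change of -1.24 (adjusted p = 0.0492), the co-activator gene Pou2af1 -0.97 and the kinase gene Blk -0.997. Cd2 (-1.03), Dtx1 (-0.997), Ikzf3 (-0.89) and Cd3e (-0.58) fell, as did Cpm (-1.20), Chst3 (-0.99), Slc25a18 (-0.92), Gpam (-0.78) and Gpr155 (-0.77). Without 1 array the call ended in 7 of 8 fits for Gpam, in 6 each for Cd3e, Ikzf3, Pou2af1 and Spib, in 5 each for Blk and Cpm, and in 4 for Gpr155. In all 274 genes changed, 231 higher and 43 lower, 97 of them by at least 1.5-fold. The groups did not overlap in 239 of these, and over all genes in 6.72%, against 2.86% by chance. The higher share of 84.3% was 69.3% after a further quantile normalisation and 72.3% after cyclic loess, which called 114 and 101 genes. Single arrays moved the count: 8 genes passed without NeuT 24-week replicate 1, 9 without replicate 4 of that group, 641 without its replicate 2, and 22 without BALB/c 24-week replicate 3. With the neutrophil and B-cell covariates 2 genes passed, Peg3 and Usp29. The 1 planned blood-cell covariate gave 398 genes, with all 274 among them.

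Neutrophil genes led the lists at 24 weeks, where 5 of 15 rose, Ltf, Cebpe (0.62), Ngp (0.59), Cxcr2 (0.54) and S100a9 (0.53), the last named after its value was seen, with 15 higher adjusted over the list alone. The list median was 0.68 (camera adjusted p = 3.71e-15; adjusted p = 0.232 with an estimated correlation). No B-cell gene of 14 passed over all genes, with 9 lower adjusted over the list alone, and the median was -0.51 (camera adjusted p = 2.66e-09; adjusted p = 0.232 with an estimated correlation). Among 15 T and NK cell genes Gzma and Cd3e fell and Nkg7 (0.40) rose, with 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 1.85e-05; adjusted p = 0.232 with an estimated correlation). Type I interferon response genes that rose were Oas1a (0.67), Rtp4 (0.66) and Dhx58 (0.49), with the BALB/c mean of Rtp4 under the median of the negative controls, of 25, with 11 higher adjusted over the list alone (camera adjusted p = 7.05e-08; adjusted p = 0.110 with an estimated correlation). The marker list of MSCs and CXCL12-abundant reticular cells was higher by camera, though which cells gave the signal is not known. Of its 19 genes 3 rose, the growth factor binding protein genes Igfbp5 (0.69) and Igfbp4 (0.35) and the adhesion molecule gene Vcam1 (0.47). Adjusted over the list alone 7 were higher (camera adjusted p = 0.000463, and adjusted p = 0.232 with an estimated correlation). Single calls ended without 1 array in 7 of 8 fits each for Cebpe, Cxcr2, S100a9 and Igfbp5, in 6 each for Ngp, Nkg7, Rtp4 and Igfbp4, and in 4 each for Dhx58 and Vcam1. The osteoblast list was lower, with a median of -0.11, none of 15 past the threshold over all genes and none adjusted over the list alone (camera adjusted p = 0.00654; adjusted p = 0.403 with an estimated correlation).

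Other blood lineages differed as lists at 24 weeks. The granulocyte-monocyte progenitor list had 1 of 10 higher, Nkg7, and 6 higher adjusted over the list alone (camera adjusted p = 1.43e-05; adjusted p = 0.244 with an estimated correlation). The monocyte and macrophage list had 2 of 15, Itgam and Ly6c2, and 5 higher adjusted over the list alone (camera adjusted p = 0.000969; adjusted p = 0.247 with an estimated correlation). Without 1 array the Ly6c2 call ended in 4 of 8 fits. None of 13 stem and progenitor cell genes passed over all genes, with 6 higher adjusted over the list alone (camera adjusted p = 0.000122; adjusted p = 0.232 with an estimated correlation). None of 11 erythroid genes passed over all genes and none adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.000648; adjusted p = 0.567 with an estimated correlation). The ribosomal protein list had a median of 0.13 (camera adjusted p = 3.45e-05; adjusted p = 0.567 with an estimated correlation), hypoxia and glycolysis 0.13 (camera adjusted p = 0.000648; adjusted p = 0.244 with an estimated correlation) and oxidative phosphorylation 0.094 (camera adjusted p = 0.00163; adjusted p = 0.603 with an estimated correlation). Cholesterol synthesis had 0.14 (camera adjusted p = 0.00654; adjusted p = 0.511 with an estimated correlation), the immediate-early list 0.14 (camera adjusted p = 0.00945; adjusted p = 0.603 with an estimated correlation) and MHC class I 0.075 (camera adjusted p = 0.0458; adjusted p = 0.564 with an estimated correlation). In these 6 lists no gene passed over all genes, and adjusted over the list alone 1 did, in cholesterol synthesis. In all 16 of 50 lists passed, 12 upwards and 4 downwards, with fry 6, and with camera and an estimated correlation 0, with 9 at an unadjusted p under 0.05.

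**Figure D2:**
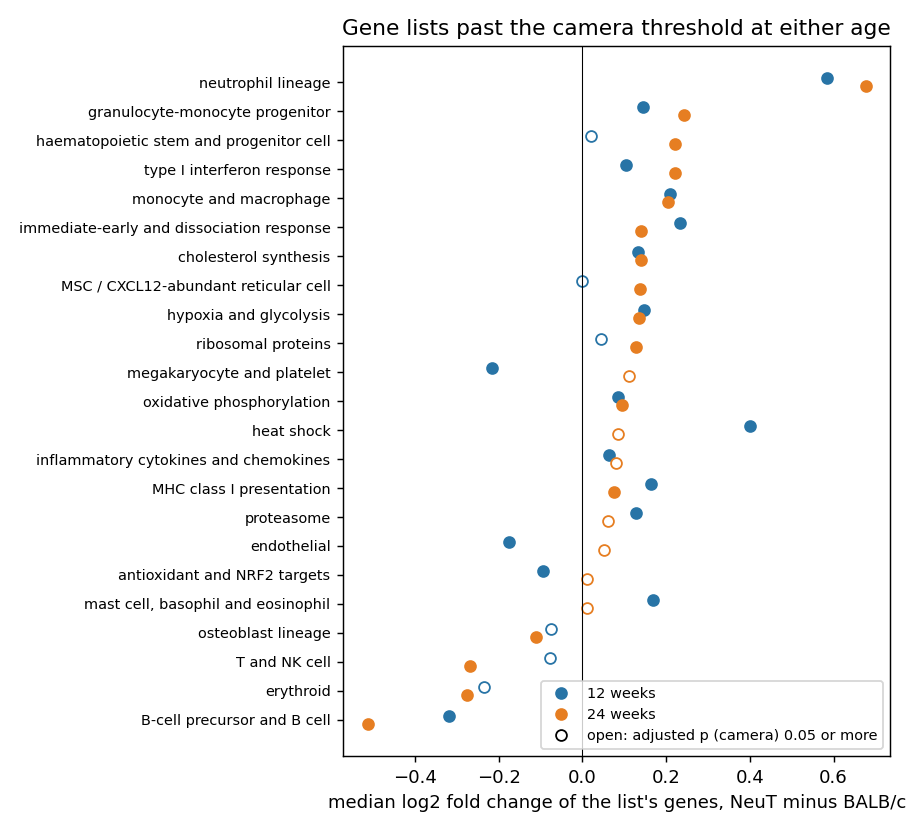
Median log2 fold change of the genes of each list, NeuT minus BALB/c (x axis), for lists that passed camera at either age (y axis), at 12 and at 24 weeks. The neutrophil list lies highest at both ages (0.59 and 0.68) and the B-cell list lowest (-0.32 and -0.51).

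**Figure D3:**
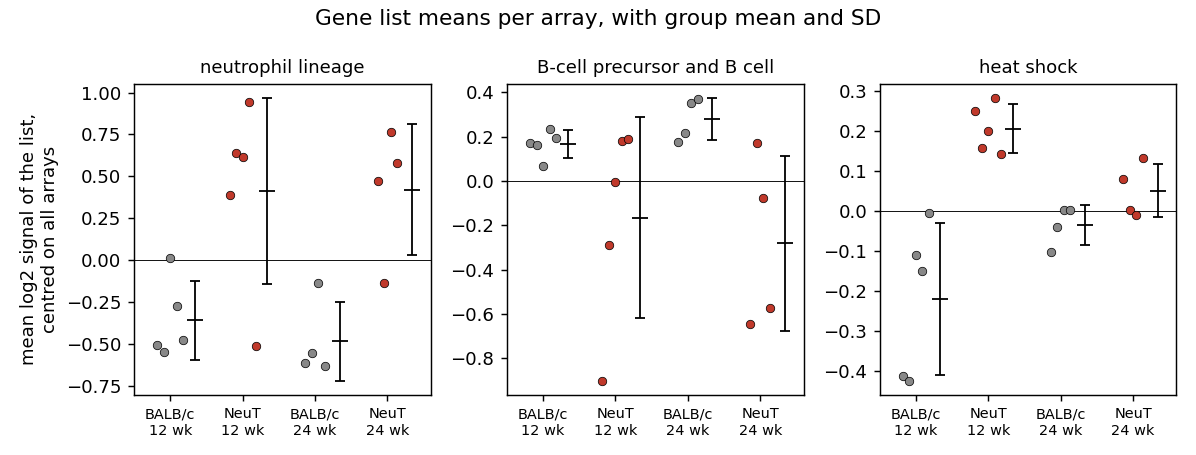
Mean log2 signal of the neutrophil, B-cell and heat-shock lists in each array, centred on all arrays (y axis), by group (x axis), with each group's mean and SD. In the B-cell list the SD was 0.45 and 0.39 in NeuT mice of 12 and 24 weeks, and 0.062 and 0.10 in BALB/c mice.

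The NeuT effects at the 2 ages, which share no arrays, were compared over all genes. Of the genes higher at 12 weeks 83 were also higher at 24 weeks, where independent calls would share 7.28, among them Peg3, Usp29, Ltf, Clec5a, Clec4a2, Oas1a, Rtp4 and Cxcr2. Of the lower genes 2 were shared, Dtx1 and Slc25a18, where independent calls would share 0.295, and the histone gene H2bc4 was called in opposite directions. Log2 fold changes at the 2 ages correlated across genes with r = 0.582; genes are not independent replicates. Of the genes called at 12 weeks 653 of 749 had the same sign at 24 weeks, and of those called at 24 weeks 259 of 274 had the same sign at 12 weeks.

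**Figure D4:**
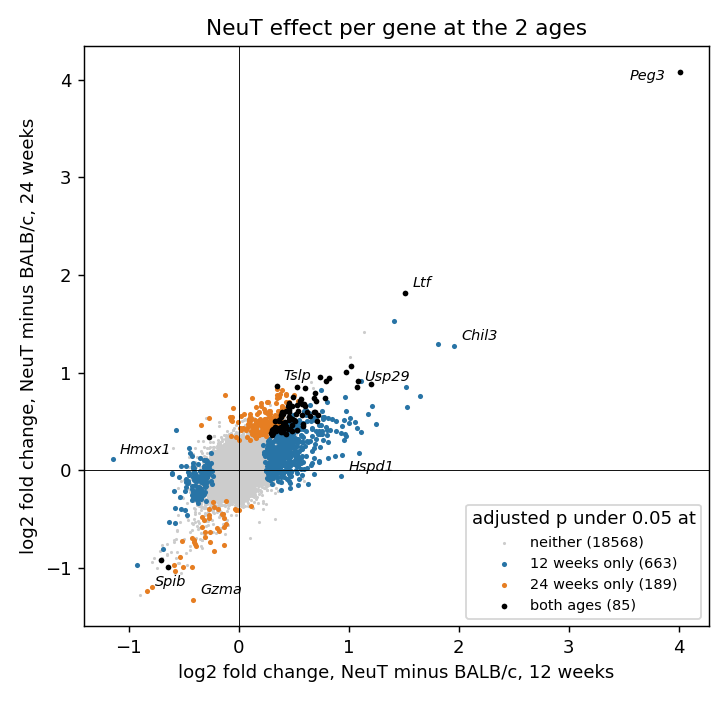
Log2 fold change of each gene, NeuT minus BALB/c, at 12 weeks (x axis) and 24 weeks (y axis), coloured by the age at which the adjusted p was under 0.05. Peg3 stands apart from the other genes at 4.01 and 4.08.

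The NeuT effect differed between the ages in 2 genes, by a test of the difference itself. Hmox1 was lower in NeuT mice at 12 weeks, while at 24 weeks it read 9.59 ± 0.30 (SD, n = 4) in NeuT and 9.48 ± 0.13 in BALB/c mice, a difference of effects of 1.26 ± 0.18 (SE, adjusted p = 0.00687). Hspd1 (Entrez gene 15510) read 11.03 ± 0.16 in NeuT and 10.10 ± 0.30 in BALB/c mice at 12 weeks and 10.75 ± 0.065 and 10.81 ± 0.12 at 24 weeks, a difference of effects of -0.996 ± 0.16 (adjusted p = 0.0352). The next genes did not pass: H2bc4, Clu, Tmem40 and Selp had differences of 0.62, 0.81, 0.57 and 0.80 (adjusted p = 0.0863, 0.0863, 0.0863 and 0.100). Tmem267, Rnd3, Hsph1 and Naaa had -0.59, -0.69, -0.70 and -0.92 (adjusted p = 0.330, 0.330, 0.339 and 0.427), with all signals of Tmem267 under the median of the negative controls. The Hspd1 call was lost in 13 of 18 fits that left out 1 array, and neither gene passed without the 3 arrays that correlate least with the others (limma; 1798 genes at an unadjusted p under 0.05), a choice made after seeing the data.

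By camera 12 of 50 lists differed between the ages, 6 with a higher NeuT effect at 24 weeks and 6 with a lower one. Lower were heat shock (camera adjusted p = 3.66e-07; adjusted p = 0.194 with an estimated correlation) and T and NK cells (camera adjusted p = 0.000147; adjusted p = 0.348 with an estimated correlation). The same held for mast cells, basophils and eosinophils (camera adjusted p = 0.000425; adjusted p = 0.384 with an estimated correlation), the immediate-early list (camera adjusted p = 0.00394; adjusted p = 0.878 with an estimated correlation), B cells (camera adjusted p = 0.00457; adjusted p = 0.878 with an estimated correlation) and MHC class II (camera adjusted p = 0.0307; adjusted p = 0.762 with an estimated correlation). Higher were megakaryocytes and platelets (camera adjusted p = 2.58e-05; adjusted p = 0.348 with an estimated correlation), endothelium (camera adjusted p = 0.000224; adjusted p = 0.194 with an estimated correlation) and antioxidant genes (camera adjusted p = 0.000224; adjusted p = 0.194 with an estimated correlation). MSCs and CXCL12-abundant reticular cells (camera adjusted p = 0.000247; adjusted p = 0.194 with an estimated correlation), niche factors (camera adjusted p = 0.00811; adjusted p = 0.348 with an estimated correlation) and ribosomal proteins (camera adjusted p = 0.0285; adjusted p = 0.906 with an estimated correlation) were higher too. Over all genes Hspd1 and Hmox1 passed and no other gene of these lists, and adjusted over the list alone 6 of 11 megakaryocyte and platelet genes, 3 of 17 antioxidant, 2 of 13 endothelial and 1 of 20 niche factor genes were higher. So adjusted 4 of 10 heat-shock, 2 of 15 T and NK cell and 1 of 14 mast cell, basophil and eosinophil genes were lower, and no gene of the other 5 lists passed. Camera with an estimated correlation passed 0 and fry 0 lists, with 7 and 6 at an unadjusted p under 0.05.

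Between 12 and 24 weeks 113 genes changed in BALB/c mice, 65 higher and 48 lower at 24 weeks. The higher share of 57.5% was 48.4% after a further quantile normalisation, 40% over all probe sets, 33.6% without BALB/c 24-week replicate 4 and 84.6% without BALB/c 12-week replicate 5, so no direction is given for the set. Fkbp11, a gene of the secretory pathway, rose by 0.95 ± 0.19 (SE, adjusted p = 0.0256, n = 5 and 4), and Dctd (0.79), Slc39a10 (0.74), Hspd1 (0.72), Myc (0.71) and the hexokinase gene Hk2 (0.69) rose too. The complement inhibitor genes Cd59a (-0.92) and Cd59b (-0.79), the transcription factor gene Sox6 (-0.80), Rec114 (-0.77), Tmod1 (-0.75) and Nxpe2 (-0.73) fell. Without 1 array the call ended in 7 of 9 fits each for Nxpe2 and Tmod1, in 6 each for Fkbp11, Cd59a, Cd59b, Rec114 and Sox6, and in 5 for Hk2. Of 23 hypoxia and glycolysis genes 3 rose, Hk2, Egln3 and Pfkl, with 9 higher adjusted over the list alone (camera adjusted p = 3.26e-07; adjusted p = 0.192 with an estimated correlation). Of 15 skeletal muscle genes 1 fell, Pvalb, with 7 lower adjusted over the list alone (camera adjusted p = 1.26e-05; adjusted p = 0.310 with an estimated correlation). Single calls ended without 1 array in 7 of 9 fits for Pvalb, in 6 for Pfkl, and in 5 for Egln3. In all 13 lists passed, with adjusted p = 0.192 to 0.713 with an estimated correlation. Without BALB/c 24-week replicate 1 no gene passed (limma; 2405 at an unadjusted p under 0.05), and without replicate 3 of that group 589 did.

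In NeuT mice 7 genes changed with age. Hmox1 rose by 0.90 ± 0.13 (SE, adjusted p = 0.00598, n = 5 and 4), and Rhoj (0.70), the P-selectin gene Selp (0.65), Bace1 (0.53) and the tetraspanin gene Cd151 (0.42) rose, while Ear10 (-0.64) fell. Oosp2 had a value of -0.65, with all signals under the median of the negative controls. Without 1 array the call ended in 6 of 9 fits for Rhoj and in 5 each for Bace1, Cd151, Ear10 and Oosp2. Atp2a1, Serpinb2 and Samd11 did not pass, at -0.95, -0.61 and -0.71 (adjusted p = 0.0509, 0.0509 and 0.0639). No gene of the skeletal muscle list (15 genes) passed over all genes, with 6 lower adjusted over the list alone (camera adjusted p = 1.01e-07; adjusted p = 0.131 with an estimated correlation). The hypoxia and glycolysis list had none of 23 past the threshold and 8 higher adjusted over the list alone (camera adjusted p = 5.05e-07; adjusted p = 0.131 with an estimated correlation), and the erythroid list none of 11 and 5 lower adjusted over the list alone (camera adjusted p = 5.05e-07; adjusted p = 0.416 with an estimated correlation). In all 17 lists passed, with adjusted p = 0.131 to 0.706 with an estimated correlation. Single arrays moved the count of genes that changed with age in NeuT mice, from 1 without NeuT 12-week replicate 4 to 177 without NeuT 24-week replicate 2.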

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

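Of the tests in this part, those on Usp29, on the 2 covariates, on single arrays, on mouse ID rank (with each ID of 1 mouse) and on a lower share of B-lineage cells alone were chosen only after the result was seen.

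Peg3 and Usp29 were higher in NeuT mice at both ages. A sequence variant under the Peg3 probes alone cannot be told apart: Usp29 has its own probe set and rose by 0.85 at 24 weeks, which was to count against it, but its highest signal, 7.10, lies under the median of negative controls (7.34), where a change decides nothing. A different mix of neutrophils and B cells is argued against by Peg3's log2 fold change at 12 weeks, 4.12 with the 2 covariates. A haplotype around Peg3 cannot be told apart either. With Usp29 left out, 2 of the 40 nearest measured genes, Zfp28 and Zfp954, were called at either age. That equals the median of 18671 windows (95th percentile 5). A bound at the median lies within the spread of such windows and was set too wide to decide. Many of the 40 are named as olfactory or vomeronasal receptor genes (Olfr, Vmn), and whether these cells express them was not tested. An effect of the transgene, the tumours or the colony on these genes stays open as an untested hypothesis.

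Neutrophil genes were higher and B-cell genes lower as lists by camera in NeuT mice (adjusted p = 0.271 and 0.515 with an estimated correlation at 12 weeks, 0.232 and 0.232 at 24 weeks), although beads against Gr1, CD11b and B220 should remove such cells; S100a9, abundant in neutrophils, read 12.43 ± 0.11 (SD, n = 5) in BALB/c and 12.78 ± 0.32 in NeuT mice at 12 weeks. Different shares of these cells in the RNA may account for it (no gene of either list is in another list), but the test made cannot decide it. Within groups the members of each list varied together, with a median pairwise correlation of 0.682 for neutrophil and 0.572 for B-cell genes. Of random lists of these sizes 95% lie under 0.135 and 0.143. Ribosomal protein and proteasome genes, which mark no cell type, reached 0.727 and 0.610, so genes regulated together would give such values too. A lower share of B-lineage cells alone would raise all other lineages alike, and is argued against at 24 weeks by the neutrophil list mean, which rose over the T and NK list mean by 1.18 (SD 0.36 in BALB/c and 0.47 in NeuT mice, n = 4, no overlap) and over 6 other blood lists by 0.67 to 1.16, without overlap only for monocytes and macrophages. Without any 1 array at least 82.9% of the neutrophil shift was left, which argues against 1 array as its source. For B-cell genes 44.6% of the 12-week shift was left without NeuT 12-week replicate 1, so that a single array cannot be told apart at 12 weeks. At 24 weeks at least 78.3% of the B-cell shift was left, which argues against a single array at that age. Whether the marrow of NeuT mice holds more neutrophils, or regulates these genes otherwise, stays open and untested.

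Hmox1 was lower and, by camera, heat-shock genes were higher as a list in NeuT mice at 12 weeks and not at 24 weeks (list adjusted p = 0.271 at 12 weeks and 0.194 for the difference with an estimated correlation). The 12-week mouse IDs of the 2 groups interleave, so a steady drift over their order could hardly make a group difference, and the covariate could hardly move it. Hmox1 stood at -1.15 at 12 weeks with ID rank as covariate (-1.13 with a second ID the labels give for 1 mouse). The labels do not say that the IDs follow the order of processing. A different mix of neutrophils and B cells is argued against by the difference of effects of Hmox1, 1.26 with the 2 covariates. Stress of handling before lysis may account for the heat-shock part: with group means removed, heat-shock and immediate-early list means correlated over 18 arrays with Pearson's r = 0.802 (permutation p = 0.0173) and Spearman's rho = 0.598 (permutation p = 0.0605), and r = 0.638 without the 2 farthest arrays. A response to the tumours stays open as an untested hypothesis.

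Other splits of the same arrays gave as many genes as the real one in 1 of 100 splits at 12 weeks, the real one included (749 genes, highest other 109). The same held in 1 of 35 at 24 weeks (274, highest other 8) and 1 of 100 for age in BALB/c mice (113, highest other 22). These shares lie under the 0.05 set beforehand, which argues against chance, and are the smallest such splits can give. They do not make the counts stable: fits on only the 2 groups compared gave 1 gene at 24 weeks. For age in BALB/c mice 0 passed without BALB/c 24-week replicate 1 (limma, 2405 at an unadjusted p under 0.05). For age in NeuT mice chance cannot be excluded, with 7 of 100 (7 genes, highest other 52). For the difference of effects 3 of 100 splits gave as many (2 genes), a share under 0.05. The highest other gave 201, so other splits can far exceed the real count, and chance is not called excluded. Why that split gave 201 genes was not tested. For lists at 12 weeks 3 of 100 splits gave as many (17 lists), also a share under 0.05. Another split gave more (highest other 18), and with an estimated correlation 0 of 50 lists passed, so chance is not called excluded. For lists at 24 weeks chance cannot be excluded, with 2 of 35 (16 lists, highest other 16), nor for the difference, with 26 of 100 (12 lists, highest other 19). The correlation of effects of the 2 ages was reached in 1 of 100 splits, the real one included (0.582, highest other 0.493), which argues against chance.

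The NeuT effect differed with age, by a test of the difference, for Hmox1 (1.26) and Hspd1 (-0.996). In lists the median differences were 0.20 for MSCs and CXCL12-abundant reticular cells, 0.15 for endothelium, -0.23 for B cells, -0.24 for T and NK cells, 0.39 for megakaryocytes and platelets, and -0.18 for mast cells, basophils and eosinophils. They were 0.10 for niche factors, -0.16 for MHC class II, 0.094 for ribosomal proteins, -0.10 for immediate-early genes, -0.31 for heat shock and 0.17 for antioxidant genes. These lists differed by camera, with adjusted p = 0.194 to 0.906 with an estimated correlation, where 0 of them passed, and with fry 0 (7 and 6 of all lists at an unadjusted p under 0.05).

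A Dixon test found 1 array far from the others of its group in 15 of 408 cases, where chance gives about 1 in 20. For log2 list means these were BALB/c 24-week replicate 3 in neutrophil genes (10.29, others 9.79 to 9.87) and replicate 1 in MHC class I (10.79, others 10.98 to 11.01) and immunomodulatory factors (8.73, others 8.91 to 8.94). In BALB/c 12-week mice they were replicate 3 in monocytes and macrophages (8.90, others 8.76 to 8.79) and replicate 5 in osteoclast genes (8.62, others 8.72 to 8.75). In NeuT 12-week replicate 5 they were Wnt signalling (8.10, others 8.03 to 8.04) and the mitotic cell cycle (11.23, others 11.06 to 11.10). In NeuT 24-week mice they were replicate 4 in dendritic cell (9.19, others 9.24 to 9.25) and ribosomal protein genes (13.25, others 13.21 to 13.22) and replicate 2 in mammary epithelium (7.71, others 7.76 to 7.76). Among genes they were Clec5a in NeuT 12-week replicate 5 (9.52, others 10.14 to 10.23), Srxn1 in replicate 4 of that group (8.66, others 8.84 to 8.91), Jchain and Ikzf3 in BALB/c 12-week replicate 5 (11.26, others 11.86 to 12.03; 9.196, others 9.66 to 9.81) and Itgam in BALB/c 24-week replicate 3 (10.17, others 9.74 to 9.81).

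Outside the named genes, 73 transcript clusters without a name here passed at 12 weeks (53 higher, 20 lower) and 24 at 24 weeks (21 and 3), in a fit over all transcript clusters without the controls. In a fit over all probe sets 31 such clusters passed at 12 weeks and 0 at 24 weeks (limma, 291 at an unadjusted p under 0.05 for the latter). Of 5222 negative control probe sets 52 passed at 12 weeks in a fit over all probe sets (47 higher, 5 lower in NeuT mice), with a median absolute log2 fold change of 0.58. That is 0.996% of them, beside 20 of 1324 positive controls (1.51%) and 387 of 19572 probe sets with a gene symbol (1.98%). At 24 weeks 0 negative controls, 1 positive control and 9 probe sets with a gene symbol passed (limma, 546, 174 and 2396 at an unadjusted p under 0.05). The labels give no processing batch, so one that follows the 2 mouse models stays open.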

How the results depend on the processing

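The fits with 2 covariates, without the 3 arrays that correlate least with the others, with mouse ID rank (1 mouse has 2 IDs in the labels, and both were tried), over all transcript clusters and without Peg3 were chosen only after seeing the data. Over the alternatives run, named genes kept direction and side of the threshold in 2870 cases, were weaker in 1303, stronger in 3 and reversed in 2; lists did so in 688, 138, 0 and 3. The reversals all came with the 2 covariates: Lcn2 at 12 weeks (-0.063), Gpam at 24 weeks (0.00374), and the lists for neutrophils at 12 weeks (adjusted p = 0.873), erythroid cells (0.805) and oxidative phosphorylation (0.946) at 24 weeks. These covariates are built from the neutrophil and B-cell genes. With them counts were 4 at 12 weeks, 2 at 24 weeks, 4 for the difference, and 366 and 25 for age in BALB/c and NeuT mice, with 8 and 10 lists. In the direction of the original call, the median log2 fold change of called genes went from 0.41 to 0.28 at 12 weeks and from 0.52 to 0.31 at 24 weeks, and the median SE from 0.0981 to 0.121 and from 0.118 to 0.148, so calls ended through smaller effects and larger errors. The 1 planned blood-cell covariate gave 753 genes at 12 weeks and 398 at 24 weeks. In the order 24 weeks, difference, age in BALB/c and age in NeuT mice, a further quantile normalisation gave 114, 4, 182 and 3. Array weights gave 2088 at 12 weeks, then 577, 10, 2375 and 72. Cyclic loess gave 101 at 24 weeks and 3 for age in NeuT mice, and median centring 1 for the difference and 1 for age in NeuT mice. A filter on dim genes gave 4 for the difference and 235 for age in BALB/c mice; moderation with a trend and robust variances gave 4 for the difference and 13 for age in NeuT mice. Over all probe sets, controls included, 490 probe sets passed at 12 weeks, 10 at 24 weeks and 0 for the difference (limma, 1658 at an unadjusted p under 0.05). Of the 490 and 10, 387 and 9 had a gene symbol. Over all transcript clusters without the controls 814 passed at 12 weeks and 277 at 24 weeks, so there the drop came with the controls. Fits on only the 2 groups compared gave 1 gene (Peg3) at 24 weeks, 183 for age in BALB/c and 0 in NeuT mice (limma; 2562 unadjusted), where 1 planned blood-cell covariate gave 2. An unmoderated test per gene with unequal variances gave 9 at 12 weeks, 0 at 24 weeks (1456 unadjusted), and 13 and 0 for age in BALB/c and NeuT mice (1930 unadjusted for the latter). Asking for 1.5-fold as well gave 120, 97 and 24 at 12 weeks, 24 weeks and for age in BALB/c mice. An unadjusted p under 0.05 with 2-fold gave 25 and 17 at 12 and 24 weeks, and 1 for each other contrast. Without the 2 24-week mice whose IDs stand apart, replicate 4 of each group, 3 passed at 24 weeks, 1 for the difference and 1 for age in NeuT mice. Without the 3 arrays that correlate least 15 passed at 24 weeks, 0 for the difference, 1277 for age in BALB/c and 0 in NeuT mice (limma; 1798 and 1773 unadjusted for the zeros). Leaving out each array in turn gave 230 to 1363 genes at 12 weeks, 8 to 641 at 24 weeks, 1 to 3 for the difference, 0 to 589 for age in BALB/c mice (limma; 2405 unadjusted at the 0) and 1 to 177 in NeuT mice. The counts at 12 weeks were 316, 230, 456 and 484 without BALB/c replicates 1, 2, 4 and 5, and 498, 487, 439, 303 and 1363 without NeuT replicates 1 to 5. At 24 weeks they were 71, 154 and 22 without BALB/c replicates 1 to 3, and 8, 641 and 9 without NeuT replicates 1, 2 and 4. Without 1 array, lists passed in 17 to 22, 15 to 17 and 10 to 15 cases at 12 weeks, 24 weeks and for the difference. Over all arrays they passed with an estimated correlation in 0 cases for each (camera, with 5, 9 and 7 unadjusted). With fry they passed in 9, 6 and 0 (6 unadjusted for the last). The correlation of effects was 0.629 without dim genes, 0.464 by Spearman's rho, 0.534 with the 2 covariates, 0.570 without Peg3, and 0.479 to 0.601 without 1 array. Stricter fold criteria lower counts by construction, and for changes where none is named the cause was not tested. Peg3 passed in 26 of 26 alternatives at 12 weeks and 22 of 23 at 24 weeks, where the exception was the unmoderated test with unequal variances. The labels pair no mice across groups and their IDs all differ, so no paired fit was made. Of the genes 28.1% had a mean signal under the median of the negative control probe sets (7.34; median of genes 8.50), which limits what their fold changes show.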

Other observations

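The gene families in this part were grouped by the stem of their symbols after seeing the data, and their enrichment tests were chosen only then. Of 594 families (2376 one-sided exact tests) 2 passed. The tests treat genes as independent draws, so for family members that vary together their p-values can be too small. C-type lectin genes (Clec), many of them receptors of myeloid cells, were called higher in NeuT mice at 12 weeks in 8 of 32 cases (adjusted p = 0.0119): Clec12a, Clec2d, Clec4a1, Clec4a2, Clec4a3, Clec4a4, Clec4b1 and Clec5a. All group means of Clec4a4 lie under the median of the negative controls (7.34). Interferon-inducible Ifi genes were called higher at 24 weeks in 4 of 13 cases (adjusted p = 0.0150): Ifi204, Ifi211, Ifi27 and Ifi44l.

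With group means removed, the lists whose genes varied most closely together from mouse to mouse were erythroid (median pairwise correlation 0.823 over arrays), ribosomal proteins (0.727), neutrophils (0.682) and the proteasome (0.610). In 4 exact two-sided permutation tests of the mice within an age, unadjusted, the neutrophil list mean gave p = 0.0397 at 12 weeks and 0.0571 at 24 weeks, and the B-cell list mean 0.111 and 0.0286. The smallest exact values these designs can give are 0.00794 and 0.0286.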
